A study of Arabidopsis thaliana with 6 samples.

How the data were processed

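Gene expression was measured on 6 Affymetrix ATH1 arrays of rosette leaves from the Arabidopsis flu mutant (allele flu1-1 in the Landsberg erecta background), 1 array for each combination of treatment (paraquat or mock) and harvest time (1, 2 or 4 h). Per the labels, the leaves of 5 to 6 plants made up a sample, and RNA of 2 separate experiments was pooled before labelling, so the spread between experiments is inside each array and cannot be seen. The genotype is that of the sample labels, while the series title names only the Landsberg erecta background. Groups were taken from the sample titles. The paraquat dose is given as 20 mM in the titles and as 20 microM in the treatment protocol, and which is right was not settled here.

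The deposited table holds a signal intensity on a linear scale for each of 22810 probe sets on each array, and the software named per the submitters' processing notes is MAS5, with no version given in the sources used here. The mean of the deposited intensities after trimming 2% was 500.04 on each array, control probe sets included, so the arrays had been scaled to a common level. This scaling removes any difference in total RNA per leaf and leaves only relative changes. Detection calls were not analysed here. For arrays, precision is limited by their number, and here there is 1 per group.

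The 64 control probe sets were left out of all comparisons, which left 22746. Signals were used as deposited, on the scale log2(signal + 34). The pseudocount of 34 is the rounded 25th percentile of all signals, and it makes a log2 ratio understate the change of dim probe sets. The floor was the 40th percentile, a signal of 86.2. The paraquat effect averaged over times was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend) with harvest time as a block, 2 residual degrees of freedom and 6.26 prior degrees of freedom, on the 13837 probe sets above the floor on at least 3 of the 6 arrays. The 3 times stand in for replicates in this test, so a real change of the effect with time counts as error. The change of the effect with time was tested by adding the product of treatment and log2 of the hour, with 1 residual degree of freedom. Both tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Values after ± are moderated SEs from limma, in which the variance of a probe set is drawn toward that of other probe sets. They can be smaller or larger than the plain SE of the 3 ratios. At a single time there is 1 array per treatment, so no test was made there: probe sets at least 2-fold different were counted among those above the floor on at least 1 of the arrays compared, and set beside the same counts between mock arrays of different times.

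Gene names came from the given probe annotation, updated through the gene number to the symbols of the TAIR10.1 gene table. Exactly 1 gene was named for 13513 probe sets, several for 503 and none for 8730, and 13436 of the 13513 matched the gene table. No coordinates are printed, since no build is named by the files. Of 461 entries in 29 gene lists written from general knowledge before the data were examined, 84 had a probe set naming that gene alone, so the lists are covered in part, 7 lists had no member and 12 had the 3 tested members needed for a test. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. At each time, the median log2 ratio of a list was placed among those of 10000 random lists of the same size matched on mean expression in 20 bins. A further 27 gene families were taken from annotation symbols after the annotation had been seen and before any treatment value was computed, and 26 of them could be tested. A list of iron-deficiency genes and a second, longer list of sugar-starvation genes were written only after some of their members had been seen among the largest ratios.

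The genes named were chosen by a rule fixed before the data were examined. For the averaged effect it takes the 12 highest and 12 lowest mean log2 ratios that passed the test, with the same sign at all 3 times, filled up where fewer than 12 passed by those with the largest smallest-of-3 ratio. At each time it takes the 6 highest and 6 lowest ratios, for each list up to 4 members, and for the change with time the 6 highest and 6 lowest slopes that passed. FLU, FER1, BAP1, APX1, APX2 and ZAT12 were to be given in every array. No probe set names any of these 6 genes alone in the annotation used, so they were not analysed here. For a gene with several probe sets the rule asks for the brightest, which was applied to members of lists and families only. Among genes that passed the averaged test, the probe set with the largest mean ratio in size was taken. At single times and for slopes any probe set naming the gene alone could enter.

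The tests were tried on simulated data made from the means and spread of the 13837 probe sets, with 200 changed in each of 10 simulations. For the averaged effect, 95.1% of 2-fold and 99.6% of 3-fold changes were recovered, with 12.1 false calls on average. For the change with time, 5.8% of slopes of 0.5 and 71.9% of slopes of 1 log2 unit per doubling of time were recovered, with 9.6 false calls on average. For the gene lists, 100% of sets of 8 genes shifted by 0.5 log2 units were called by camera, and 3% of unshifted sets. The 12 tested lists had 3 to 8 tested members, and recovery for sets smaller than 8 was not simulated. Simulated genes were independent of each other, which those of a real list need not be. Simulated averaged effects were equal at all 3 times, and the noise came from the fitted model itself. Recovery of real effects, which may vary with time, can therefore be lower. Alternatives covered the scaling between arrays, the pseudocount, the filter, the variance model, the time block, the fold threshold, the set test and leaving out each time in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.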

Results

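Rosette leaves of 3-week-old flu plants grown in continuous light received a spray of paraquat, dissolved in 0.1% Tween, or a mock spray of the detergent, and were harvested 1, 2 and 4 h later. The flu mutant lacks a negative regulator of chlorophyll synthesis and overaccumulates protochlorophyllide in the dark. Paraquat, also called methyl viologen, takes electrons from photosystem I and passes them to oxygen as superoxide. Each of the 6 treatment and time combinations was measured on 1 ATH1 array, from RNA pooled over 2 experiments. Median signals lay between 157.7 and 162.0, and 59.1% to 60.8% of probe sets lay above the floor. Each array correlated best with the array of the other treatment at the same hour, with r across probe sets of 0.984 at 1 h, 0.984 at 2 h and 0.977 at 4 h. Probe sets are not independent replicates. Ratios below are log2(signal + 34) of paraquat minus mock.

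The first comparison asked which transcripts differed between paraquat and mock leaves over the 3 times. AT3G20340 was raised most among named genes, by 2.47 ± 0.29 log2 units (moderated SE, n = 3 times, limma adjusted p = 0.024). Its signals at 1, 2 and 4 h were 95.9, 62.7 and 99.1 in mock leaves and 354, 1001 and 679 with paraquat. AT4G01870 rose by 1.74 ± 0.22, AT2G41730 by 1.45 ± 0.22 and AT3G49160, which encodes a pyruvate kinase family protein, by 1.37 ± 0.14. ATMDAR2 (AT5G03630), a monodehydroascorbate reductase that regenerates ascorbate, rose by 0.99 ± 0.13, the glutaredoxin family gene AT3G62950 by 1.09 ± 0.16 and the autophagy gene ATG8E by 0.81 ± 0.10. On the lower side, AT5G05250 fell by 1.69 ± 0.17 log2 units. AT1G47400, which encodes a small peptide known to be induced by iron deficiency, fell by 1.34 ± 0.16. AT3G56360 fell by 1.17 ± 0.12 log2 units. Of these 15 named genes, counting 5 given next, AT3G20340, AT4G01870 and ATMDAR2 still passed without 1 h and 12 did not (limma adjusted p from 0.064 to 0.19), and AT3G62260 lost the threshold whichever of the 3 times was left out.

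In all, 35 probe sets were higher and 9 lower at an adjusted p under 0.05, of 13837 tested, and each had the same sign at all 3 times. Mean log2 ratios ran from 0.53 to 2.47 among the higher and from -0.74 to -1.69 among the lower probe sets. A single gene was named for 16 of the higher and 3 of the lower. The smallest adjusted p belonged to an unnamed probe set whose signal was 882, 1242 and 3080 in mock and 4588, 9590 and 13872 in paraquat leaves at 1, 2 and 4 h (mean log2 ratio 2.47 ± 0.14, limma adjusted p = 0.00082). The rule also named AT3G15450 (1.08 ± 0.15), AT5G19120 (1.05 ± 0.11), AT4G33666 (1.02 ± 0.14), AT3G62260, a protein phosphatase 2C family member (0.96 ± 0.14), and AT4G27450 (0.89 ± 0.12) among the genes that rose. Of the 16 higher, 12 were named this way. The others were LHCB4.2, given with its list, and AT4G15680 (0.79 ± 0.11), AT3G06070 (0.76 ± 0.11) and AT4G05070 (0.67 ± 0.10), chosen after their values were seen. Of the genes that fill the lower side of the rule without passing the test, AT1G61670 had a mean log2 ratio of -0.72 ± 0.12 (limma adjusted p = 0.065) and AT5G64870 one of -0.70 ± 0.12 (limma adjusted p = 0.078). The other 7 were AT2G17280, AT5G57250, AT1G64380, AT2G21530, AT3G15350, AT1G21370 and AT5G34930. The number of calls depended on the model: no probe set was called by limma without the time block (375 at an unadjusted p under 0.05) or without the filter on low signals (1821), and 1 was called without the variance trend. Without 1 h 5 were higher and 2 lower, without 2 h 49 and 8, and without 4 h 57 and 14. The 44 calls kept their sign under these settings, as they had to. Leaving out the block, the filter or the variance trend does not alter a mean ratio, and every call had 1 sign at all 3 times.

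**Figure D1:**
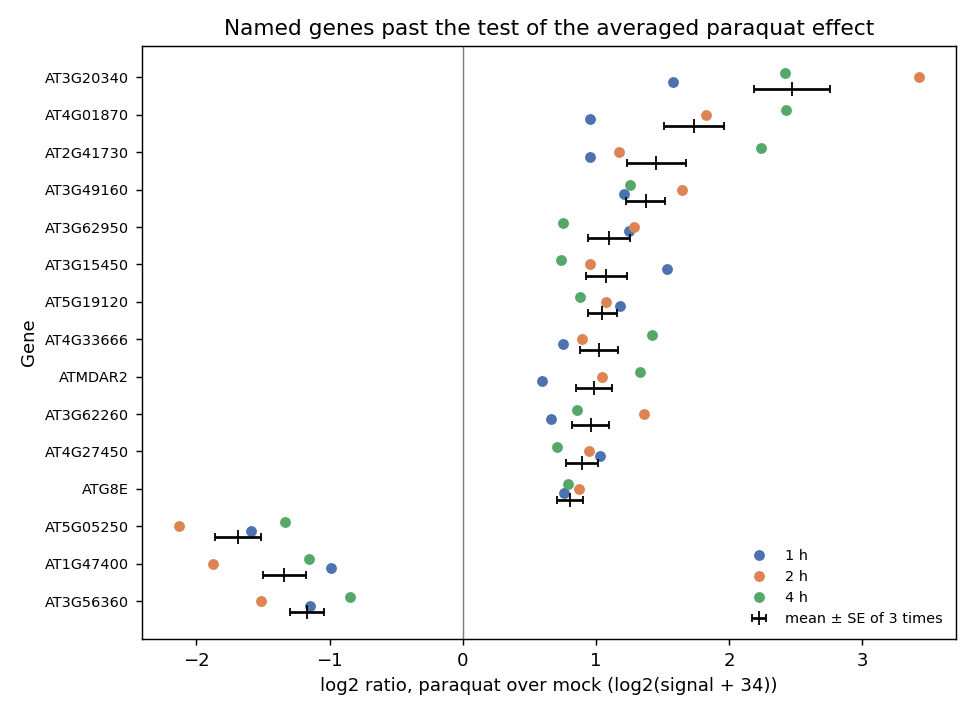
Log2 ratio of paraquat over mock (horizontal axis, log2(signal + 34)) for the 15 genes named by the rule that passed the test of the averaged effect (vertical axis). Each gene has 1 point for each of the 1, 2 and 4 h array pairs, with the mean ± moderated SE in black. The 12 higher genes lie above 0 and the 3 lower genes below 0 at each time.

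The second comparison set paraquat against mock at each time. At 1 h, AT2G25450 had a log2 ratio of 1.67, AT3G20340 one of 1.58 and AT3G15450 one of 1.53, while AT2G40230 stood at -2.07, AT5G10830 at -1.90 and the plastid-encoded photosystem I gene psaA at -1.59 (signal 8107 in mock and 2676 in paraquat leaves). At 2 h, AT3G20340 had the highest ratio of a named gene, 3.42, and AT5G05250 the lowest, -2.13. With a pseudocount 4 times smaller AT5G05250 stood at -2.44. AT1G15490 (-3.08), AT2G26520 (-2.73), AT1G10980 (-2.70) and AT3G15800 (-2.68) then lay below it. At 4 h, the small heat shock protein gene AT2G29500 stood at 3.57, AT1G76600 at 3.39, AT1G05575 at 3.02, AT4G37290 at 3.00, the small heat shock protein gene AT1G54050 at 2.94 and the UDP-glycosyltransferase gene UGT73B5 at 2.92. The lowest ratios at 4 h were -2.18 for AT5G45630 and -2.09 for AT1G11210, followed by -1.73 for LTI30, a dehydrin known from cold and drought. This order depends on the pseudocount. With one 4 times smaller, AT5G01080 went from -1.60 to -2.15, below LTI30, and AT5G45630, with a paraquat signal of 34.6, to -2.72.

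At least 2-fold differences were found for 65 higher and 46 lower probe sets at 1 h, 64 and 41 at 2 h, and 172 and 72 at 4 h. With 1 array per treatment these counts have no replicate check. As background, mock arrays differed between times by more: 159 probe sets were at least 2-fold higher and 296 lower at 2 h than at 1 h, 376 and 255 at 4 h than at 2 h, and 499 and 545 at 4 h than at 1 h. Of the probe sets above the floor at both times, 11 were at least 2-fold higher at both 1 and 2 h. The number was 15 at both 2 and 4 h and 6 at both 1 and 4 h. Independent lists would share 0.19, 0.55 and 0.61 if every probe set were equally likely to pass, which dim ones need not be. Across the 13837 tested probe sets, ratios correlated at r = 0.30 between 1 and 2 h, 0.22 between 2 and 4 h and 0.05 between 1 and 4 h. At 3-fold the counts were 5 higher and 9 lower at 1 h, 11 and 8 at 2 h, and 58 and 11 at 4 h. Several of the largest ratios rest on a signal well below the floor of 86.2: AT4G37290 had a signal of 7.22 in mock leaves at 4 h, and AT5G10830 one of 16.1 in paraquat leaves at 1 h.

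**Figure D2:**
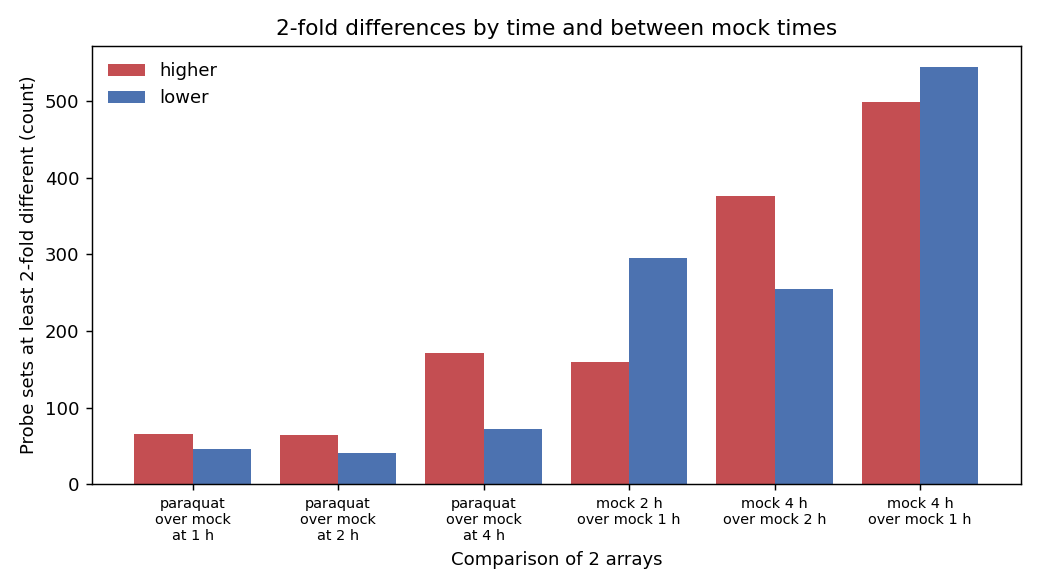
Number of probe sets at least 2-fold higher (red) or lower (blue) in the array named first than in the other (vertical axis), for paraquat over mock at each time and between mock times (horizontal axis). The paraquat counts are 65 and 46 at 1 h and 172 and 72 at 4 h, and each mock pair gives more in total than the paraquat pair at any time.

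The third comparison asked whether the paraquat effect changed with time. The ratio of AT1G05575 rose by 1.42 ± 0.19 log2 units per doubling of time (moderated SE, limma adjusted p = 0.0042), from 0.17 at 1 h to 3.02 at 4 h. That of AT1G76600 rose by 1.24 ± 0.16. UGT73B5 rose by 1.17 ± 0.19 per doubling. AT5G10830 (1.46 ± 0.21), AT2G40230 (1.22 ± 0.18) and AT1G22810 (1.31 ± 0.17) went from a negative ratio at 1 h to a positive ratio at 4 h. In the other direction, AT2G37870 went from 1.16 at 1 h to -1.54 at 4 h (slope -1.35 ± 0.16), AT5G39520 from 1.15 to -1.29 (slope -1.22 ± 0.18) and the calmodulin-like gene CML41 from 0.55 to -1.23 (slope -0.89 ± 0.11). The ratios of AT1G11210, AT2G25625 and AT1G05340 fell with time too, with slopes of -1.18, -1.02 and -0.94. Some slopes rest largely on the mock arrays. From 1 to 4 h the signal of AT2G25625 went from 123 to 996 in mock and from 168 to 288 in paraquat leaves. That of AT1G05340 went from 365 to 2793 and from 515 to 1021. For AT1G22810 it went from 419 to 35.2 and from 237 to 219. For AT1G05575, given first above, it went from 841 to 156 in mock and from 953 to 1507 in paraquat leaves. AT1G11210 changed on both sides, from 203 to 655 and from 252 to 128. So did AT5G39520, from 152 to 557 and from 380 to 207. In all, 59 slopes were positive and 48 negative at an adjusted p under 0.05, and 49 of the 107 probe sets named 1 gene. A single probe set was called in both this test and the averaged one, AT4G01870 (slope 0.73 ± 0.09, limma adjusted p = 0.0038). The counts were 166 and 128 after quantile normalization and 200 and 137 with arrays centred on the 75th percentile, and none was called by limma without the filter (1958 at an unadjusted p under 0.05).

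Of the gene lists, heat shock and chaperone genes were among those with high ratios at 4 h. The median log2 ratio of the 6 members above the floor on at least 1 array was 0.09 at 1 h, -0.36 at 2 h and 1.71 at 4 h, at percentiles 78.3, 0.98 and 100 of random lists, and 4 of the 6 were at least 2-fold higher at 4 h. These were AT2G29500 (signal 24.4 in mock and 658.5 in paraquat leaves), AT1G53540 (ratio 2.77), AT5G51440 (2.41) and AT5G37670 (1.01), all genes of small heat shock proteins. AT2G29500 and AT1G53540 passed the floor on the paraquat 4 h array alone. AT5G51440 also varied without paraquat, with mock signals of 136, 616 and 130 at 1, 2 and 4 h, against 836 with paraquat at 4 h. With members chosen in 2 other ways, fixed after seeing the data, the 4 h median was 1.01 both for all 7 named members and for the 3 above the floor on 3 arrays, at percentile 100 each. Their medians were -0.00 and -0.15 at 1 h (percentiles 60.2 and 18.6), where the sign was thus not kept, and -0.27 and -0.53 at 2 h. Abscisic acid, drought and cold genes lay the other way at 4 h, with a median of -0.91 over 4 members at percentile 0, led by LTI30 (signal 1430 in mock and 408 in paraquat leaves) and COR15A (864 and 342). The same list had a median of 0.24 at 2 h, at percentile 98.0. Stress transcription factor genes had a median of 0.73 at 4 h over 4 members, with STZ at 1.08, WRKY6 at 0.94, WRKY22 at 0.52 and WRKY53 at -0.37. Other lists were high at 4 h too, with medians of 1.38 for xenobiotic detoxification (percentile 100), 0.60 for mitochondrial stress (99.9), 0.26 for tetrapyrrole synthesis (99.8), 0.17 for photosynthesis (99.1) and 0.47 for auxin genes (98.9), after -0.49 at 1 h and -0.39 at 2 h. Single times have no test, and averaged over times 0 of the 3 tested heat shock members, 0 of the 4 abscisic acid, drought and cold members and 0 of the 4 stress transcription factor genes passed the test over all probe sets. Adjusted over the list alone, 0 heat shock members, 0 abscisic acid, drought and cold members, and 2 higher and 1 lower stress transcription factor genes passed. Without 2 h, STZ (limma adjusted p = 0.046) and WRKY6 (limma adjusted p = 0.047) passed over all probe sets. Without 2 h, these 3 lists were called by camera (adjusted p = 0.0034, 0.0011 and 0.012). None of the 3 calls held without 2 h with an estimated correlation (adjusted p = 0.62 each) or with fry (adjusted p = 0.63, 0.52 and 0.52), tests added after seeing the data. Without 4 h the median of the tested heat shock members was -0.37 and that of the abscisic acid, drought and cold list 0.04, so both directions rest on 4 h.

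**Figure D3:**
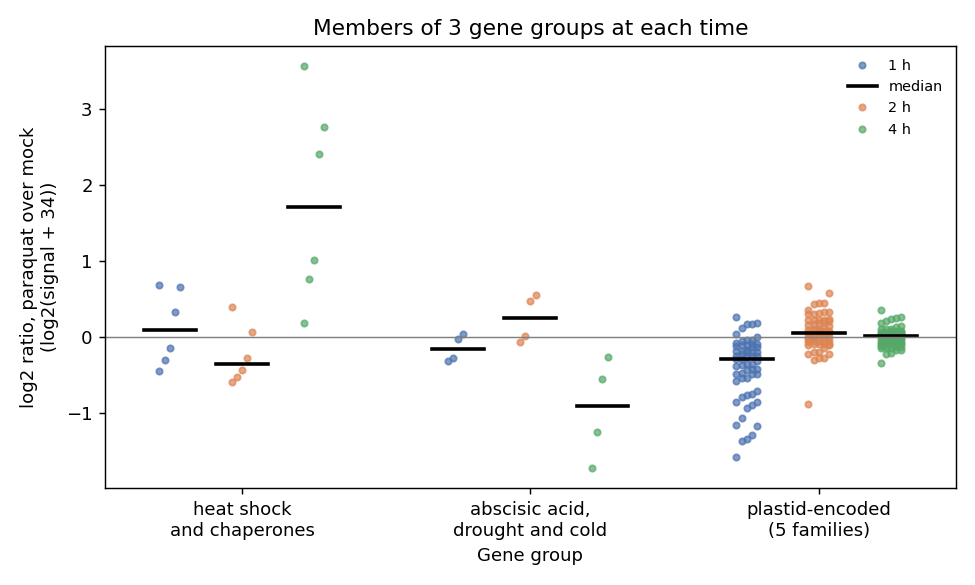
Log2 ratio of paraquat over mock (vertical axis, log2(signal + 34)) for members of the heat shock list (6), of the abscisic acid, drought and cold list (4) and of 5 plastid-encoded families (61) at 1, 2 and 4 h (horizontal axis: group, colour: time), with black bars at the medians. The heat shock median is 1.71 at 4 h, that of the abscisic acid, drought and cold list is -0.91 at 4 h, and many plastid-encoded genes lie below 0 at 1 h.

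Averaged over times, xenobiotic detoxification was called by camera, with 3 tested members and a median of 0.53 (adjusted p = 0.017). The call was lost with an estimated correlation (adjusted p = 0.77), with fry (adjusted p = 0.38) and without 4 h (adjusted p = 0.076). UGT73B5 led it with a mean ratio of 1.60 ± 0.37, followed by AER, an alkenal reductase, with 0.53 ± 0.24, and AT2G04050, a transporter of the MATE family, with 0.52 ± 0.22. None of the 3 passed the test over all probe sets, and 1 passed adjusted over the list alone. Without 2 h UGT73B5 passed (limma adjusted p = 0.034). The other 11 tested lists were not called. Of 7 antioxidant enzyme genes, ATMDAR2 rose and 6 did not pass, among them SAPX (0.14 ± 0.11), GR (0.18 ± 0.10) and GR1 (0.10 ± 0.12). Of 8 photosynthesis genes, LHCB4.2, an antenna protein of photosystem II, rose by 0.58 ± 0.09 (limma adjusted p = 0.042) and 7 did not pass. LHCB4.2 lost the threshold without 1 h (limma adjusted p = 0.17) and without 2 h (0.076). Adjusted over the list alone, 1 gene passed in each of these lists. Of the 4 members of the mitochondrial stress list, AT2G41730 rose, while NDB2 had -0.37 ± 0.09 and AT2G21640 had 0.59 ± 0.17. Adjusted over the list alone, 2 passed upward and 1 downward, and without 2 h the list was called by camera (adjusted p = 0.012) but not with an estimated correlation (adjusted p = 0.62) or fry (adjusted p = 0.52). With limma, 0 of 4 glutathione transferase genes, 0 of 8 tetrapyrrole synthesis genes and 0 of 3 auxin genes passed, adjusted over the list alone as well. The list of genes known to respond to singlet oxygen in flu held members on both sides, with AT1G05575 at 3.02 at 4 h and AT5G64870 at -0.70 ± 0.12 averaged over times, and 1 of its 5 genes passed in each direction adjusted over the list alone. Its median of 0.12 differed in sign from its camera direction, which was downward, as did those of the tetrapyrrole (0.02) and auxin (0.09) lists. Of 3 reference genes, AT4G34270 stood at 0.15 ± 0.11, AT2G28390 at -0.05 ± 0.10 and PEX4 at 0.02 ± 0.09. Guard cell markers AT1G22690 (0.13 ± 0.10) and FMA (-0.10 ± 0.15) did not pass the test.

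Among the families taken from gene symbols, 0 of 26 were called by camera, the smallest adjusted p being 0.16. The median was below 0 and the camera direction upward for aldehyde dehydrogenases, beta-glucosidases, trichome birefringence-like proteins and thioredoxins. The plastid-encoded families had low ratios at 1 h on the array pair in which psaA was low. The median was -0.27 for 20 photosystem genes, -0.19 for 12 cytochrome b6f and ATP synthase genes, -0.39 for 10 NDH genes, -0.30 for 15 ribosomal protein genes and -0.63 for 4 RNA polymerase genes. At 2 h the medians were 0.18 for NDH, 0.11 for ribosomal protein and 0.28 for RNA polymerase genes, at percentiles 99.4, 98.7 and 98.7, and 0.00 and -0.06 for the first 2 families. At 4 h the same 5 medians lay between -0.12 and 0.14. The 1 h signs held after quantile normalization and centring on the 75th percentile, while the photosystem median changed sign at 2 and 4 h, and the cytochrome b6f and ATP synthase median at 2 h, all close to 0. On the paraquat 1 h array the control probe set for 25S ribosomal RNA had a signal of 307.7, against 92.8 to 130.5 on the mock arrays and 111.4 and 243 on the paraquat arrays of 2 and 4 h. The ratio of the 3' to the 5' signal of the GAPDH control was 1.15 there and 0.89 to 1.05 on the others.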

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

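The plastid comparison below and the test of the mock 4 h rise were chosen only after the values they rest on had been seen, as was the signal level asked of the mitochondrial genes.

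The paraquat/mock log2 ratio differed between times, by the test of its change with time, for 15 of the named genes. With 1 array pair at each time, a changing paraquat effect cannot be told apart from a deviant array. The ratio of psaA was -1.59 at 1 h, 0.05 at 2 h and 0.03 at 4 h, so its slope rests on 1 h. Per doubling of time the log2 ratio rose by 1.46 for AT5G10830, 1.42 for AT1G05575, 1.31 for AT1G22810, 1.24 for AT1G76600, 1.22 for AT2G40230, 1.17 for UGT73B5, 0.81 for psaA, 0.75 for AER and 0.73 for AT4G01870. The slope was -1.35 for AT2G37870, -1.22 for AT5G39520, -1.18 for AT1G11210, -1.02 for AT2G25625, -0.94 for AT1G05340 and -0.89 for CML41. The 107 calls of this test were set against other splits of the arrays. Of the 10 splits of the 6 arrays into 3 and 3, only 4 part each time pair and allow the slope to be fitted, and 1 of the 4, the real one, gave as many as 107, the highest other giving 1. For the averaged effect, 1 of the 10 splits, the real one, gave as many as 44 calls, and the highest other gave 12. Splits with 12 calls part only 1 time pair, and those other than the real one that part each pair gave 0. The latter swap the treatments at 1 time, so a ratio with the same sign at all times turns into error there. Few calls are due in them in any case, and they give no background for the 44 calls. With so few splits no share under 0.05 can be had for either test.

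The number of probe sets at least 2-fold different was largest at 4 h, with 172 higher and 72 lower. Array scaling or a wider distribution of signals at 4 h is argued against. After quantile normalization the 4 h count was still 2.03 times that at 1 h (231 and 114). Quantile normalization does not remove noise of single probe sets on 1 array, so it decides nothing about such noise. For the 172 higher probe sets, an unusual mock 4 h array stays open: from 2 to 4 h they had a median change of 0.55 on the paraquat arrays and of -0.48 on the mock arrays, but choosing them by their 4 h ratio favours both signs, so these values decide nothing. The 72 lower probe sets, LTI30 and COR15A among them, had a median change of 1.25 on the mock arrays and of -0.20 on the paraquat arrays. Their choice favours both signs too. A rise on the mock arrays that is missing with paraquat would give the unequal sizes. But mock arrays changed more from 2 to 4 h in general, with 376 probe sets at least 2-fold higher and 255 lower. The paraquat arrays gave 235 and 116. Choosing by the 4 h ratio could therefore give unequal sizes as well, so they decide nothing. Whether the rise on the mock arrays belongs to mock-treated leaves in general or to this 1 array stays open, since there is no second mock array at 4 h.

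Plastid transcripts were lower on the paraquat 1 h array, 61 of 69 plastid-encoded genes having a negative ratio against 27 of 69 at 2 h and 34 of 69 at 4 h. A fall of plastid-encoded transcripts as a whole stays open, the median of the other 68 genes being -0.31, between the bounds of -0.5 and -0.25 set for and against it. The mock 1 h array had the highest median plastid level (12.47 on the log2 scale) and the paraquat 1 h array the lowest (11.96), the other 4 lying between 12.17 and 12.31, so both arrays of the pair contribute. A lower yield of organelle RNA in that preparation could also give this; the median ratio of 8 mitochondrial-encoded genes at 1 h was 0.071, but their median signal of 132.5 is close to the floor, so it decides nothing. A biological effect of paraquat at 1 h cannot be told apart from the preparation of this 1 sample.

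Control probe sets outside the comparisons were higher on the paraquat 1 h array than on any mock array: the 25S ribosomal RNA control had 307.7 against at most 130.5, and the actin 5' control 1329 against at most 571.6.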

How the results depend on the processing

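Alternatives were fixed before the data were examined, except that requiring both arrays above the floor, the 2 other set tests without 2 h and other choices of list members were added after seeing the data. No value that passed its test changed sign under an alternative. For the averaged calls this was fixed in advance where a time, the block, the filter or the variance trend was left out. Of named genes and lists that did not pass, 23 averages changed sign under at least 1 alternative, 17 of them without 4 h, among them the heat shock list (-0.37) and the abscisic acid, drought and cold list (0.04). Of list medians at single times under other choices of members, that of heat shock at 1 h changed sign, from 0.09 to -0.15 and -0.00. Mock and paraquat arrays of the same hour were paired through the time block. No paired analysis was possible on replicate numbers because each group holds 1 array. Where a count moved by more than 1.5 times, its value follows, and the cause was not tested except where the setting itself changes what is counted. Averaged effect: 23 probe sets were higher after quantile normalization, 0 higher and 0 lower without the filter or without the time block, and 1 higher and 0 lower without the variance trend. Leaving out each time in turn gave 5 to 57 higher and 2 to 14 lower, on fewer arrays. Change with time: 166 rising and 128 falling after quantile normalization, 200 and 137 with arrays centred on the 75th percentile, 125 and 107 with a pseudocount 2 times larger, 0 and 0 without the filter, and 76 falling with the floor at the 60th percentile. A fit without a time has no residual degrees of freedom for this slope and was not run. Gene lists: 0 called with an estimated correlation or with fry. With the floor at the 60th percentile 0 were called too, but there the xenobiotic list had under 3 members left and was not tested. Without each time in turn, 0 to 4 were higher and 0 to 1 lower. Without 2 h the heat shock list (adjusted p = 0.0034), the abscisic acid, drought and cold list (0.0011), stress transcription factors (0.012) and mitochondrial stress (0.012) were called by camera, but 0 lists with an estimated correlation (adjusted p = 0.62 for each of the 4) or fry (0.52 to 0.63).

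The 2-fold counts moved with what counts as a dim signal, as they must. With a pseudocount 4 times smaller they were 112 higher and 100 lower at 1 h and 119 and 71 at 2 h. With one 2 times larger they were 37 and 26 at 1 h, 35 and 19 at 2 h, and 94 higher for mock 2 h over 1 h. Without the filter they were 134 and 148 at 1 h, 146 and 134 at 2 h, 117 lower at 4 h, 243 higher for mock 2 h over 1 h and 399 lower for mock 4 h over 2 h. With the floor at the 60th percentile they were 42 and 17 at 1 h, 31 and 13 at 2 h, and 100 higher for mock 2 h over 1 h. With both arrays above the floor they were 43 and 17 at 1 h, 32 and 14 at 2 h, and 103 higher for mock 2 h over 1 h. At 3-fold they were 5 and 9 at 1 h, 11 and 8 at 2 h, 58 and 11 at 4 h, 29 and 85 for mock 2 h over 1 h, 100 and 64 for mock 4 h over 2 h, and 172 and 189 for mock 4 h over 1 h. Under each of these settings the count at 4 h exceeded that at 1 h and 2 h in total.

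Of the values of single genes and lists under all alternatives, 871 counted as unchanged, 51 moved, 27 lost the threshold and 7 passed it. Averages and slopes counted as unchanged when their call was kept, whatever their size. Values at single times counted as unchanged when they stayed within the spread. The 871 therefore include 28 changes of sign of averages that did not pass. Of the 44 averaged calls, 31 were shared with those after quantile normalization and 42 with those after centring on the 75th percentile. AT2G41730, AT3G62950, AT3G62260 and LHCB4.2 lost the threshold after quantile normalization, and AT2G41730 also with centring on the 75th percentile or the larger pseudocount. Dim signals limit the ratios of single times: at 2 h those of AT1G10980 and AT2G26520 rest on paraquat signals of 7.81 and 7.27.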

Other observations

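The iron list and its test were chosen only after its values had been seen, and the starvation list after 4 of its members had been seen, its other members not.

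Several families not yet described had ratios away from 0. Of 7 calmodulin-like genes above the floor, the median log2 ratio was 0.55 at 1 h (percentile 100 of random lists), with CML23 at 1.28, CML43 at 0.82 and CML38 at 0.80, and it was -0.06 at 2 h and 0.01 at 4 h. CML23 had a mock signal of 19.8 at 1 h, below the floor, and its ratio was 1.89 with a pseudocount 4 times smaller and 0.91 with one 2 times larger. The paraquat 1 h array, on which all 1 h ratios rest, stood apart in its controls, with a 25S ribosomal RNA signal of 307.7, against 92.8 to 243 on the other arrays, and an actin 5' signal of 1329, against 527 to 584. The 7 plant U-box ubiquitin ligase genes had medians of 0.27, 0.27 and 0.17 at 1, 2 and 4 h, at percentiles 99.3, 99.2 and 96.7, with PUB26 at 1.05 at 1 h and PUB23 at 1.47 at 4 h. Of 11 autophagy genes, ATG8E passed the averaged test and 10 did not, and the median was 0.24 at 1 h, 0.10 at 2 h and -0.07 at 4 h, at percentiles 99.9, 93.4 and 32.4. These signs held after quantile normalization and centring on the 75th percentile. None of these families was called averaged over times, with camera adjusted p = 0.22 for each of calmodulin-like and U-box genes and 0.16 for autophagy genes.

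A first hypothesis concerns AT3G15450, AT5G19120, AT4G27450 and ATG8E, which rose at each time and are known to rise under sugar starvation. If paraquat leaves shared such a response, other genes known to rise under starvation should be higher too, with a median above 0.3. Of a list of 32 such genes drawn up from general knowledge, 12 were named on the array, and the 8 not seen before had a median mean log2 ratio of 0.31, just above that bound, at percentile 100 of random lists. AT1G23390 stood at 0.74 ± 0.13 and AKINBETA1 at 0.39 ± 0.12, while ATL8 (-0.07 ± 0.16) and AT2G32150 (-0.12 ± 0.16) did not follow. None of the 8 passed the test on its own, and their median was 0.40 at 1 h, 0.34 at 2 h and 0.05 at 4 h. A starvation-like response in the first 2 h may therefore be worth following up, as a hypothesis found and tested on the same arrays.

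A second hypothesis is that genes induced by iron deficiency were lower with paraquat, from AT1G47400 and AT5G05250. Of 33 list entries 9 were named, and only 2 other induced genes were above the floor: PYE (-0.38 ± 0.18) and AT1G18910 (-0.03 ± 0.12). Their median of -0.21 lies between the bounds set for and against it, so the test with 2 genes decides nothing.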
